A study of Mus musculus with 2 samples.

How the data were processed

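Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for acetylated histone H3 (H3K27ac), a mark found at active promoters and enhancers, was measured in hindbrain tissue of C57BL/6 (B6NCrl) mouse embryos at 12.5 days. There was 1 group with 2 biological replicates, each a pool of male and female embryos. Replicate 1 pooled 120 embryos and replicate 2 pooled 88. The series holds no second condition, so every comparison is between the replicates, between peaks and shifted peaks, or between lists of genes within these libraries. No library of another tissue, age or mark was analysed here.

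The deposited files are 4 peak lists on the mm10 build. Per the text notes deposited with each sample, 1 list was called on replicate 1 against its own control and 1 on replicate 2 against another control. A combined list was called on both replicates together against both controls. A replicated list was derived from the combined list and both single-replicate lists. The peak caller, its version, its threshold and the rule that makes a peak replicated are not given in the sources used here. Column 7 of each list was taken as the fold enrichment of a peak over its background, a linear ratio computed by the authors, and columns 8 and 9 as the deposited −log10 p and −log10 q. The sources do not name these units, which were read from the column order of the format and from the values, and every fold given here rests on that reading. The smallest deposited −log10 p was 2.00 in replicate 1 and 2.01 in replicate 2. The fold enrichment is each peak's own value within its list, as the authors deposited it, and the lists were called separately. Read totals per library are not in the peak lists used here, so the depth is unknown and no interval or detection floor that needs it is given. A gene without a peak had no peak called at this unknown depth, which does not show that the mark is absent.

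Peaks on the 19 autosomes, X and Y were used. Entries of a list that overlap or touch were to be merged, but none did. Genes were the 21938 protein-coding genes of GENCODE release M21 on GRCm38, the assembly that mm10 names, with 93513 annotated transcript starts. Peaks were put in classes by their midpoint: promoter within 1 kb of a start, otherwise exon, intron or intergenic. A gene had a promoter peak where a peak overlapped the window of 1 kb either side of any of its annotated starts, and its promoter fold was that of the strongest such peak. Neighbouring genes can share a peak. Distal peaks did not overlap the 2.5 kb either side of any protein-coding start and were counted for the nearest start. Large acetylated regions were made by joining replicated peaks within 12.5 kb of each other and were ranked by the bases that peaks cover. All coordinates are given on mm10, counted from 1.

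Overlap required 1 bp. The overlap of the replicates and the class shares were tested by permutation, with 1000 random circular shifts of the peaks within each chromosome. The overlap test was one-sided. For each class the smaller of the p values for more and for fewer peaks was taken, without doubling. The smallest p that these shifts can give is 0.001. Promoter peaks were tested for 30 gene lists of 414 symbols, all of which matched the annotation. The lists covered hindbrain, midbrain and forebrain regulators, Hox groups, neural and other cell types and pathways, and the test was Fisher's exact test, two-sided, against all other protein-coding genes, with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. Distal peaks per list were compared as the percentile of the list's median among 10000 random lists of the same size matched within 10 bins of territory length, the stretch of chromosome nearer to a gene's starts than to any other. The log2 ratio of promoter fold between replicates was compared in the same way, matched within 10 bins of mean fold. Ties with random lists were split evenly between below and above. Lists at percentile 97.5 or above, or 2.5 or below, are called outside the middle 95% of random lists, or apart. Chance gives this for 5% of lists where values have few ties. Distal counts have many ties at small values, which leave little room to come out low, so 5% need not hold for them. Anterior and posterior Hox genes, and hindbrain and forebrain regulators, were compared by Fisher's exact test, two-sided. Distal peaks of hindbrain and forebrain regulators were compared by a two-sided permutation test with 100000 resamples, without matching on territory length. Genes are not replicates, so these tests describe the peak lists of these libraries.

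The lists, tests and rule for naming genes were fixed before the data were examined. The rule names the 10 replicated peaks of highest fold that both replicates overlap, the 10 such distal peaks and the 15 largest regions. It also names up to 4 members per list with the highest promoter fold, up to 4 members in alphabetical order without a promoter peak, all Hox genes, and the 5 genes at each end of the ratio between replicates. The alternatives were promoter windows of 500 bp and 2.5 kb, 1 start per gene, the combined list, a −log10 q of at least 2 or 5, each replicate's list alone, other overlap rules, other distal and joining distances, −log10 p or ranks in place of fold, and no matching on territory. The 1 start per gene was the upstream end of the gene's whole annotated span, which can lie far from its other starts. The alternatives' shifted comparisons used 100 shifts. A count of long non-coding starts, 1 start per gene for the comparisons of 2 lists, and random lists matched on the number of CpGs within 500 bp of a start were added after the data were seen.

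The statistics were tested on simulated data. For the overlap of the replicates, with copies of 60% of the 84095 peaks of replicate 1 planted in a simulated list, 60.5% were found, against 3.31% in shifted peaks. For promoter peaks by gene list, over 21938 genes, 97.6% of simulated lists of 20 genes with peaks at 95% were called, against 0.950% of lists at the background rate. All background genes in it had the same independent chance of a peak. In the data that share ran from 0.410% to 94.5% with the number of CpGs at the promoter. The 0.950% is therefore not the rate of calls for random lists that differ in CpG number. For the difference between replicates by gene list, over the same 21938 genes, 86.0% of lists of 15 genes raised by 1 SD came out high and 4.00% of unchanged lists came out apart. That simulation drew independent values and let them rise slightly with the matching bins. With a rise 10 times as steep, which was tried first, 45.0% of raised lists came out high and 2.00% of unchanged ones came out apart, so matching within coarse bins loses power where values depend strongly on the matched property. The reported test used 11666 genes, which can share peaks, and lists of differing sizes, so these rates need not carry over to it. The comparison of distal counts was not simulated. Simulated lists were drawn at random over all bins. They cannot show how often a list comes out high when its genes crowd the long end of a territory bin. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.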

Results

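H3K27ac was profiled in embryonic mouse hindbrain at 12.5 days in 2 biological replicates of pooled embryos. The hindbrain gives rise to the medulla, pons and cerebellum. The replicate 1 list held 84105 peaks and the replicate 2 list held 90568, with median widths of 286 and 299 bp. On the main chromosomes these peaks covered 41.5 and 47.0 Mb. The combined list held 104827 peaks covering 59.7 Mb, and the replicated list held 53332 peaks covering 47.1 Mb, with a median width of 595 bp. Median fold enrichment was 3.51 in replicate 1, 3.41 in replicate 2, 3.02 in the combined list and 3.96 in the replicated list. Sequencing depth is unknown from the peak lists. Folds below are those deposited for the replicated list, followed where stated by those of replicate 1 and replicate 2.

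Of the 10 strongest replicated peaks, 9 overlapped the promoter window of a protein-coding gene. The peak at Sp3, a zinc finger transcription factor (chromosome 2, 72978303 to 72981898), had the highest fold, 63.5, with 55.8 in replicate 1 and 53.1 in replicate 2. A peak of 10969 bp on chromosome 5 (123132921 to 123143889) spanned the start of Setd1b, a histone H3 lysine methyltransferase. It reached the promoter window of Rhof but not its start, and had a fold of 59.8, with 53.0 and 38.3 in the replicates. The other 8 of the 10 strongest were at Zc3h6 (58.6), Zc3h4 (54.8), the RNA-binding protein gene Pcbp1 (54.7), the Krüppel-like factor gene Klf7 (54.6), Tnrc18 (54.1), Arrdc3 (53.3), the histone H4 lysine methyltransferase gene Kmt5b (53.0), and an intergenic site. That site lay at the start of the long non-coding RNA 1810026B05Rik, 16.4 kb from the nearest start of the chromatin remodeler gene Chd2, with a fold of 53.9.

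The first question was how far the replicates found the same sites. Of the 84095 replicate 1 peaks on the main chromosomes, 51239 (60.9%) were overlapped by a replicate 2 peak. In the other direction it was 48523 of 90558 (53.6%), and the Jaccard index of covered bases was 47.7%. Shifted peaks gave means of 3.51%, 3.22% and 0.957%, and all 3 values exceeded every shift (permutation p = 0.001, the smallest possible). Overlap followed strength: in the top 10% by fold, 8408 of 8409 replicate 1 peaks and 9052 of 9055 replicate 2 peaks were found in the other replicate. In the lowest 10% it was 39.0% and 30.6%. When peaks had to share at least 50% of both lengths, the overlap was 35.0% and 32.5%.

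Peaks called in only 1 replicate were weaker, narrower and less often at promoters. Median fold was 3.17 for peaks of replicate 1 only against 4.09 for shared peaks, and 2.93 against 4.14 in replicate 2. Median width was 210 against 415 bp and 225 against 486 bp. Promoter midpoints made up 10.2% of the peaks of replicate 1 only and 11.2% of those of replicate 2 only, against 31.4% and 30.9% of shared peaks. Introns held 51% and 50.3% of them, against 36.7% and 37.0% of shared peaks. These differences were not tested.

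**Figure D1:**
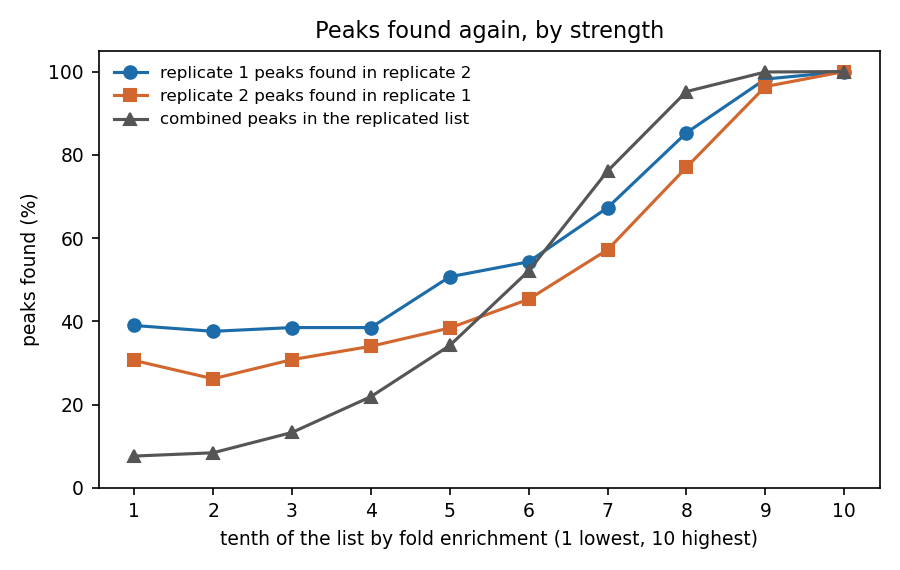
Percent of peaks found again (vertical axis) in 10 bins of the deposited fold within each list (horizontal axis), for replicate 1 in replicate 2, replicate 2 in replicate 1, and combined peaks in the replicated list. The top 10% was found almost completely in all 3 cases, while in the lowest 10% the shares were 39.0%, 30.6% and 7.63%.

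The replicated list kept 53323 of the 104813 combined peaks, or 50.9% (Wilson 95% interval 50.6 to 51.2, counting error only). It kept 7.63% of the lowest 10% by fold and all of the top 10%. Every replicated peak was an entry of the combined list. Of the replicated peaks, 41907 (78.6%) were overlapped by a peak of each replicate. Another 19149 combined peaks (18.3%) were overlapped by neither single-replicate list.

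At those 41907 peaks the folds of the replicates were compared peak by peak. Pearson's r of log2 fold was 0.857 and Spearman's rho was 0.735, across peaks, which are not independent replicates. The log2 ratio of replicate 1 over replicate 2 had a median of -0.02 and an SD of 0.44, and 2.52% of peaks differed at least 2-fold. Within the top 10% by fold, Spearman's rho was 0.673, and within the narrow range of the lowest 10% it was 0.032, with an SD of the log2 ratio of 0.38 and 1.17% of peaks at least 2-fold apart. The lists were called separately against different controls, so these values describe the lists.

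Replicated peaks concentrated at promoters and were scarcer between genes than shifted peaks. Promoters held 28.0% of midpoints against 4.06% ± 0.183 (SD, 1000 shifts), 6.89 times as many. Intergenic sites held 29.9% against 57.5% ± 0.897, and introns 38.9% against 35.6% ± 0.777 (permutation p = 0.001 for each of these classes, the smallest possible). Exons held 3.19% against 2.87% ± 0.121 (permutation p = 0.00699). Among peaks with −log10 q of at least 5, the exon and intron shares were 2.78% and 34.6%, below the shifted means, and neither passed the test. With a promoter window of 2.5 kb the exon share was 2.29% and did not pass.

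**Figure D2:**
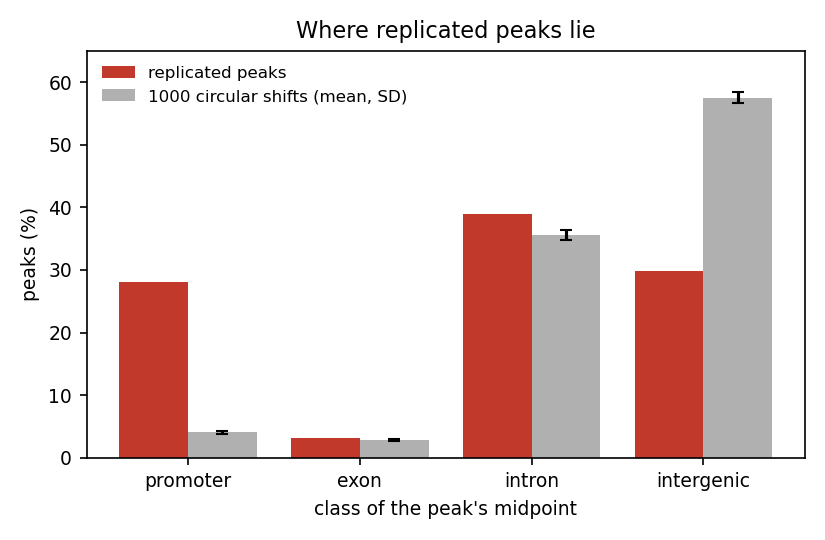
Percent of peak midpoints (vertical axis) in promoters, exons, introns and intergenic sequence (horizontal axis), for the replicated peaks and for 1000 circular shifts, whose bars give the mean and error bars the SD. Promoters held 28.0% of replicated peaks against 4.06% of shifted peaks, and intergenic sites 29.9% against 57.5%.

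Of 21938 protein-coding genes, 11907 (54.3%) had a promoter peak in the replicated list, 12165 in replicate 1 and 12581 in replicate 2. Of the 30 gene lists, 7 had more members with a promoter peak than other genes, 7 had fewer and 16 did not pass (Fisher's exact test with Benjamini-Hochberg adjustment). The test does not account for CpG number. Random lists matched on it gave means of 5.74 lists called higher and 2.31 called lower other than Hox.

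All 22 axon guidance genes had a promoter peak (exact adjusted p = 5.44e-05, Fisher's exact test), led by the ephrin receptor genes Ephb2 (fold 28.6) and Epha7 (21.6), the ephrin gene Efnb2 (18.2) and the semaphorin receptor gene Plxna2 (17.1). Of 22 genes of differentiating neurons, 21 had one (exact adjusted p = 2.98e-04), with the highest folds at Myt1l (30.8), Nhlh2 (27.6), the neuronal tubulin gene Tubb3 (24.4) and the splicing factor gene Rbfox3, which encodes NeuN (24.2). Neurod4 had none. Of 22 neural progenitor genes, 19 had one (exact adjusted p = 0.00593), led by the RNA-binding protein gene Msi1 (33.6), the Notch ligand gene Dll1 (23.0), the Notch target Hes5 (20.6) and the proneural factor gene Ascl1 (17.9). Dbx1, Dbx2 and Olig2 had no promoter peak in any of the 4 lists. Against random lists matched on the number of CpGs at the promoter, the neural progenitor list was inside the middle 95% (86.4% against a mean of 79.2%).

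All 16 Notch pathway genes had a promoter peak (exact adjusted p = 3.60e-04), among them the Notch effector gene Rbpj (24.7), Dll1, Hes6 (21.9) and Hes5. Of 12 Hedgehog pathway genes 11 did (exact adjusted p = 0.0197): the receptor gene Ptch1 had a fold of 37.1, Gas1 27.7, Cdon 24.7 and the transcription factor gene Gli3 19.3, while Hhip had none. Counting only 1 start per gene left 10 of the 12 Hedgehog genes, with an exact adjusted p of 0.0724. Against lists matched on CpG number, the Notch (100% against 88.7%) and Hedgehog (91.7% against 78.8%) lists were inside the middle 95%. That range reached 100% for both. The Notch list, already at 100% (percentile 92.8), could not come out high, and the Hedgehog list had little room to. The Wnt pathway did not pass, with 11 of 19 (exact adjusted p = 0.821). Its feedback gene Axin2 had a fold of 38.5, Fzd3 19.6, Tcf7l2 15.2 and Fzd10 12.1, and Dkk1, Rspo1, Rspo3 and Sp5 had no replicated promoter peak. The retinoic acid pathway did not pass either, with 9 of 12 (exact adjusted p = 0.320). The receptor genes Rara (27.5), Rxra (17.9) and Rarg (9.11) and the binding protein gene Crabp2 (7.81) had peaks. The synthesis gene Aldh1a2 and the degradation genes Cyp26a1 and Cyp26c1 did not, but the degradation gene Cyp26b1 did.

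Cell cycle genes had promoter peaks in 14 of 17 cases (exact adjusted p = 0.0521), with E2f1 (11), Ccna2 (8.45), Mcm6 (8.07) and Ccnd2 (7.92) the strongest and Bub1, Ccnb1 and Mcm3 without one. The list passed in the combined list, in replicate 1 alone and with 1 start per gene. All 17 housekeeping genes had a promoter peak (exact adjusted p = 2.98e-04), with Actb at 49.8, Ywhaz at 41.8, Eef1a1 at 25.3 and Polr2a at 25.2.

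Markers of cells outside the neural tube went both ways. Of 16 genes of mesenchyme and meninges, the connective tissue around the brain, 15 had a promoter peak (exact adjusted p = 0.00452), including Foxc1 (10.9), Prrx1 (10.7), Foxc2 (8.55) and Pdgfra (8.23), with Alx1 the exception. In replicate 1 alone it was 13 of 16 and the call was lost (exact adjusted p = 0.0944). Genes of neural crest and sensory ganglia had peaks in 11 of 13 cases without passing (exact adjusted p = 0.0828). Eya1 (19.6), Tfap2a (15.1), Pou4f1 (9.32) and Tfap2b (9.17) were the strongest, and the nerve growth factor receptor gene Ntrk1 and the myelin gene Plp1 had none.

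Blood, vessel, muscle, liver and germ cell markers had fewer promoter peaks than other genes. It was 2 of 15 erythroid genes (exact adjusted p = 0.00452), namely Tal1 (6.53) and Slc4a1 (3.00), with none at Alas2, Epor, Gata1 or Gypa. It was also 2 of 15 microglia and macrophage genes (exact adjusted p = 0.00452), C1qb (3.26) and Csf1r (2.91), with none at Adgre1, Aif1, C1qa or C1qc. Of 13 skeletal muscle genes only Mymk had one (3.11; exact adjusted p = 0.00420), and Acta1, Actc1, Chrng and Des did not. None of 11 hepatocyte genes had one (exact adjusted p = 9.11e-04), among them Afp, Ahsg, Alb and Apoa1. Of 11 germ cell genes, only Dazl (4.97) did (exact adjusted p = 0.00941), and Acrv1, Ddx4, Prm1 and Prm2 did not. Of 14 endothelium and pericyte genes, Pdgfrb (5.44), Erg (4.12) and Flt1 (3.26) had one (exact adjusted p = 0.0334), and Cdh5, Cldn5, Emcn and Esam did not. The endothelium call was lost with a 2.5 kb window, in the combined list (7 of 14, exact adjusted p = 0.655) and in each replicate alone, and the muscle call was lost with a 2.5 kb window (exact adjusted p = 0.0537). Against lists matched on CpG number, erythroid (13.3% against 16.1%), microglia (13.3% against 14.4%), muscle (7.69% against 28.3%) and hepatocyte (0% against 20.9%) genes were inside the middle 95%. That range reached 0% for hepatocyte and microglia genes. The hepatocyte list, already at 0% (percentile 2.60), could not come out low, and the microglia list had little room to. Epidermis did not pass, with 2 of 9 (exact adjusted p = 0.149), the keratin genes Krt10 (19.6) and Krt1 (5.01), and with none at Dsg3, Ivl, Krt14 or Krt15. With 1 start per gene it was 0 of 9, without Krt10 and Krt1, and passed as lower (exact adjusted p = 0.00607).

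The remaining neural lists did not pass. Floor plate genes had promoter peaks in 7 of 10 cases (exact adjusted p = 0.452), with the guidance genes Ntn1 (11.7), Slit3 (9.94), Slit2 (9.63) and Slit1 (6.84) and without Arx, Foxa1 and Nkx2-9. Astrocyte genes had them in 6 of 10 (exact adjusted p = 0.809), with Nfib (29.7), Nfia (16.6), the glutamate transporter gene Slc1a2 (15.8) and Sox9 (13.6) and without Aldh1l1, Aqp4, Gfap and S100b. Genes of neurotransmitter identity had them in 6 of 13 (exact adjusted p = 0.679), with the transporter genes Slc17a6 (16.3) and Slc32a1 (13.7), Ddc (13.4) and Gad2 (12) and without Chat, Dbh, Slc18a3 and Slc5a7. It was 9 of 13 in replicate 1 alone and 8 of 13 in replicate 2 alone, both above other genes, and neither passed. For oligodendrocyte lineage genes it was 5 of 12 (exact adjusted p = 0.482), with Pdgfra, Sox10 (5.88), Cspg4 (3.26) and Nkx2-2 (3.03). The myelin gene Mbp also had a peak, while the myelin genes Mag, Mobp and Mog and their regulator Myrf had none. With −log10 q of at least 5 the oligodendrocyte list had 2 of 12 and passed as lower (exact adjusted p = 0.0397). For roof plate and choroid plexus genes it was 4 of 13 (exact adjusted p = 0.160), with Lmx1a (6.22), Msx2 (5.13), Foxj1 (4.23) and Msx1 (3.26) and without Aqp1, Clic6, Folr1 and Gdf7. Motor neuron genes had 3 of 10 (exact adjusted p = 0.282), with Phox2b (6.22), Isl1 (4.33) and Lhx4 (3.14) and without Chat, Isl2, Lhx3 and Mnx1, but 6 of 10 in replicate 1 alone.

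**Figure D3:**
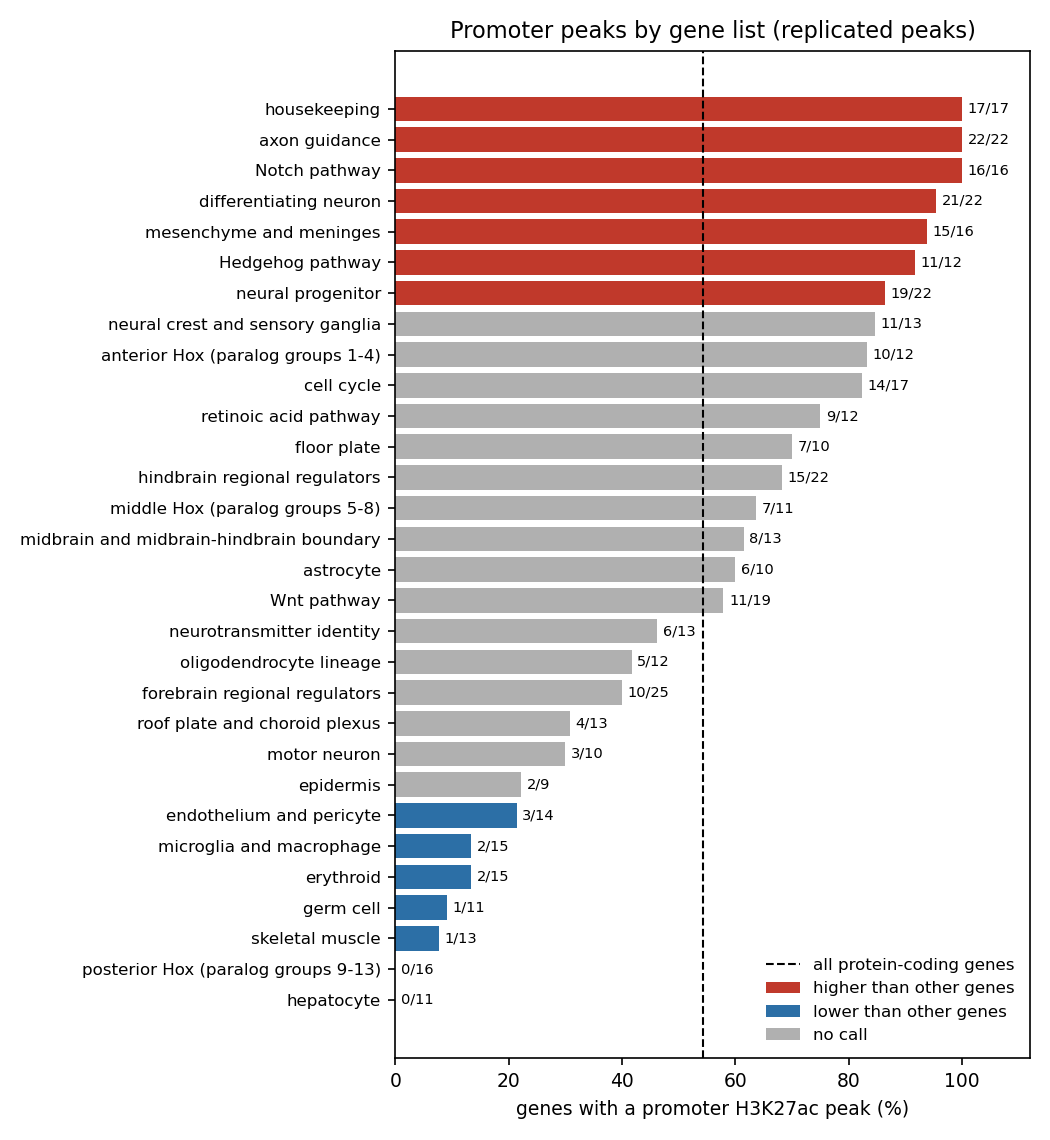
Percent of the genes of each of the 30 lists with a promoter peak in the replicated list (horizontal axis), with the number of genes beside each bar. Red and blue bars passed Fisher's exact test after adjustment, grey bars did not, and the dashed line is the 54.3% of all protein-coding genes. Axon guidance, Notch pathway and housekeeping genes reached 100%, and posterior Hox and hepatocyte genes had none.

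Hox genes, which give cells their position along the body axis, were marked at their anterior members. Of the 12 genes of paralog groups 1 to 4, 10 had a replicated promoter peak, and of the 16 genes of groups 9 to 13 none did (Fisher's exact test, p = 5.03e-06). Each replicate alone had 10 of 12 against 1 of 16 (exact p = 4.97e-05), the posterior exception being Hoxa9 (2.65) in replicate 1 and Hoxb9 (2.93) in replicate 2. With 1 start per gene, an alternative for this comparison chosen after seeing the data, Hoxa3, Hoxd3 and Hoxd4 had no promoter peak, the fold at Hoxc4 was 3.04 in place of 13.4, and it was 7 of 12 against 0 of 16 (exact p = 6.69e-04). That start was the upstream end of the gene's annotated span. For Hoxd3 it lay at 74711927, while the peak at another of its starts began at 74730032. These losses therefore depend on which start was taken. By group, peaks were found at 1 of 3 genes in group 1, 2 of 2 in group 2, 3 of 3 in group 3, 4 of 4 in group 4, 3 of 3 in group 5, 2 of 3 in group 6, 1 of 2 in group 7 and 1 of 3 in group 8.

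In the HoxA cluster on chromosome 6, Hoxa2 had a fold of 32.3, with 16.4 in replicate 1 and 34.9 in replicate 2. Hoxa4 had 21.3, Hoxa3 10.1, Hoxa1 8.35, Hoxa5 7.78 and Hoxa6 3.14, while Hoxa7, Hoxa9, Hoxa10, Hoxa11 and Hoxa13 had no replicated promoter peak. In HoxB on chromosome 11, Hoxb2 had 18.7, Hoxb5 12.1, Hoxb8 5.90, Hoxb7 5.28 and Hoxb6 3.96. Hoxb3 and Hoxb4 shared a peak from 96316855 to 96347457 with a fold of 16.5, and Hoxb1, Hoxb9 and Hoxb13 had none. In HoxC on chromosome 15, Hoxc4 had 13.4 and Hoxc5 10.6, with none at Hoxc6 and Hoxc8 to Hoxc13. In HoxD on chromosome 2, Hoxd3 had 20.7 and Hoxd4 9.01, with none at Hoxd1 and Hoxd8 to Hoxd13. Hox genes lie close together and share peaks and annotated starts, so their promoters are not independent. As lists against all other genes, the posterior Hox genes passed (exact adjusted p = 5.44e-05), and the anterior (exact adjusted p = 0.0828) and middle ones, groups 5 to 8 (7 of 11, exact adjusted p = 0.809), did not. With 1 start per gene Hoxb6, Hoxb8 and Hoxc5 also had no promoter peak, and the middle list fell to 4 of 11, below other genes (exact adjusted p = 0.461). The start taken for Hoxc5 was at 102967443, while the peak at another of its starts began at 103013983.

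**Figure D4:**
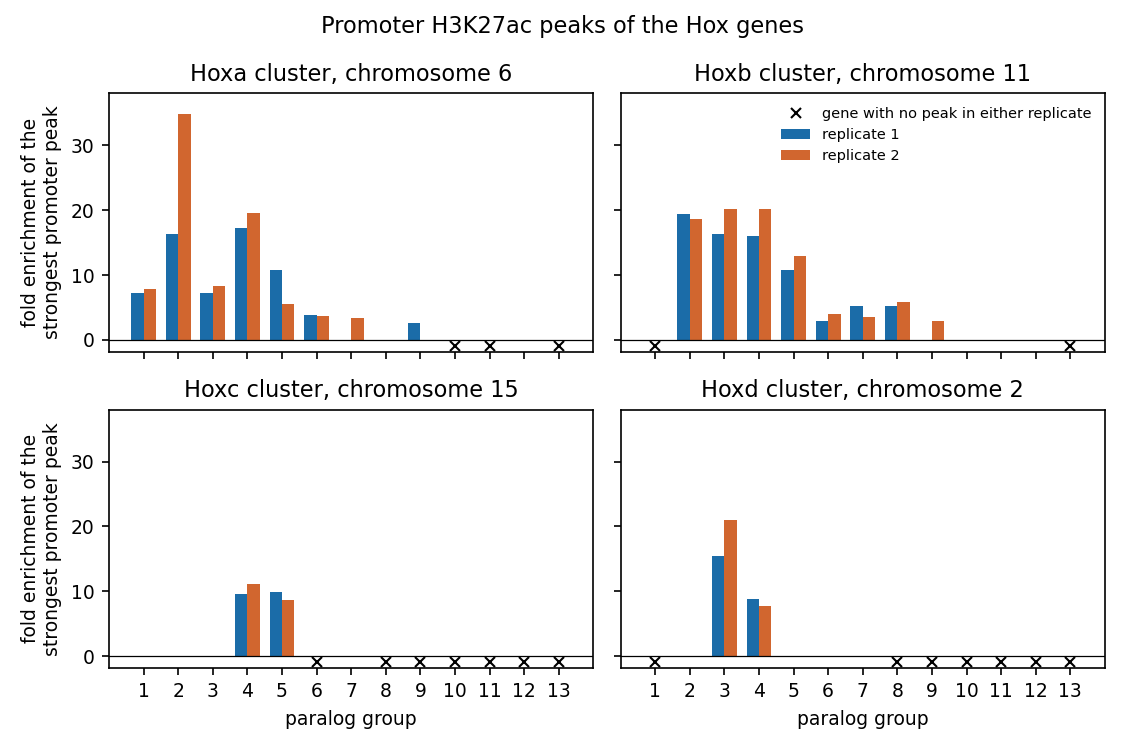
Deposited fold of the strongest promoter peak (vertical axis) for every Hox gene by paralog group (horizontal axis) in the 4 clusters, with replicate 1 in blue and replicate 2 in orange. Crosses mark genes with no peak in either replicate; a group number without a bar or cross has no gene in that cluster. Peaks end at group 9 or before in each cluster.

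Regulators of hindbrain identity were set against those of the forebrain. Of 22 hindbrain regulators, 15 had a replicated promoter peak, against 10 of 25 forebrain regulators, which did not pass (Fisher's exact test, p = 0.0799). The comparison passed in replicate 1 (17 against 10, exact p = 0.0174), in replicate 2 (19 against 12, exact p = 0.00689), in the combined list (20 against 10, exact p = 5.80e-04) and with −log10 q of at least 5 (14 against 7, exact p = 0.0200). It also passed with 1 start per gene, chosen after seeing the data (15 against 9, exact p = 0.0415). It did not pass with promoter windows of 500 bp (15 against 10, exact p = 0.0799) or 2.5 kb (15 against 11, exact p = 0.143). The strongest hindbrain regulators were the Hox cofactor genes Pbx3 (47.7), Meis1 (38.5) and Meis2 (26.1), followed by Irx3 (19.7). Atoh1, Barhl1, Barhl2 and Egr2 had no replicated promoter peak but had weak ones in the combined list, at 3.42, 2.39, 2.71 and 2.84. Among forebrain regulators Bcl11b stood at 26.1, with 26.0 and 17.8 in the replicates. Lhx2 (6.84), Satb2 (6.78) and Otx1 (5.38) followed, and Arx, Emx1, Eomes and Fezf2 had no promoter peak in any list. Against all other genes neither list passed (hindbrain exact adjusted p = 0.282, forebrain exact adjusted p = 0.246). The hindbrain list passed as higher in the combined list (exact adjusted p = 0.00656) and in replicate 2 alone (exact adjusted p = 0.0120), and the forebrain list as lower with −log10 q of at least 5 (exact adjusted p = 0.0479). Against lists matched on CpG number, the hindbrain list was below the mean but inside the middle 95% (68.2% against 79.6%), and the forebrain list was below the middle 95% (40.0% against 77.3%).

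Hindbrain regulators had 12.1 ± 17.0 distal peaks per gene (SD, 22 genes) and forebrain regulators 2.32 ± 5.91 (SD, 25 genes), a difference of 9.77 (permutation p = 0.00850). The test was not matched on territory length. Length-matched random lists had medians of 1.00 distal peaks for hindbrain and 0 for forebrain regulators. Few genes carried much of each mean. Of 266 distal peaks in the hindbrain list, Pbx3 had 51, Meis2 50 and Meis1 43. Of 58 in the forebrain list, Bcl11b had 29. The lists' own medians were 3.50 and 0. The difference was 19.1 in the combined list, 14.1 in replicate 1 alone and 15.4 in replicate 2 alone. The list for midbrain and the midbrain-hindbrain boundary, a signalling centre at the border of the hindbrain, had promoter peaks in 8 of 13 cases (exact adjusted p = 0.809). En1 (10.6), Pou4f1 (9.32), En2 (9.17) and Pax2 (7.41, with 32 distal peaks) were the strongest. Fgf17, Fgf8, Otx2 and Pitx3 had no replicated promoter peak.

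Of the replicated peaks, 34692 (65.1%) were distal, with a median fold of 3.61 against 5.78 for the others. In 10 of the 30 lists the median number of distal peaks per gene lay above the middle 95% of matched random lists. None lay below it, but random lists had medians of 0 to 1.5, which leaves little room for a list to come out low. Axon guidance genes had a median of 19 against 1.5 in random lists, with 47 at Ephb2 and 36 at Plxna2. Hedgehog genes had 9.50 against 0.5, with 25 at Gas1 and 20 at Ptch1. Neural progenitor genes had 4.50 against 0.5, differentiating neuron genes 4.00 against 0 (57 at Rbfox3, 52 at Myt1l), midbrain genes 4.00 against 0, hindbrain regulators 3.50 against 1.00 and Notch genes 3.00 against 0. Wnt genes (3.00 against 1.00), neurotransmitter genes (2.00 against 0) and oligodendrocyte genes (1.5 against 0) were at percentiles from 97.8 to 98.2. Each of these last 3 lists fell back inside the middle 95% in either replicate alone. In the other direction, the retinoic acid pathway (percentile 97.2) and anterior Hox genes (49.8) came out high in each replicate alone, at 99.2 and from 99.7 to 99.8, astrocyte genes in replicate 1 alone (98.7) and housekeeping genes in replicate 2 alone (99.0). Forebrain regulators were at percentile 29.6, with a median of 0.

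The strongest distal peaks lay in intergenic sequence on chromosomes 2, 3, 4, 5, 7 and 13. After the site near Chd2, with a second one 76.1 kb from that gene (fold 39.5), came a peak 4.83 kb from the start of Sirt4 (chromosome 5, 115488720 to 115490384) at 52.4. A stretch of chromosome 2 held 3 of them: one at the start of the long non-coding RNA Gm14488 (30715029 to 30727105) at 49.1, one at 30689498 to 30696850 with 48.2 and one at 30656800 to 30662368 with 39.0. Their nearest protein-coding starts belonged to 1700001O22Rik and Cstad, between 54.4 and 88.0 kb away. A peak 76.4 kb from Mef2c, a neuronal and muscle transcription factor gene, lay at the starts of C130071C03Rik and Gm26803 (chromosome 13, 83724058 to 83734517) with 48.8. Others lay at a start of Gm12974, 46.8 kb from Rps6ka1 (40.4), and at a start of Zswim6, 153.2 kb from Smim15 (38.1). Zswim6 was counted here among the long non-coding genes and not the protein-coding ones, so a peak at its start counts as distal. The last lay at Mir124-2hg, a host gene of the neuronal microRNA miR-124 (chromosome 3, 17784650 to 17792294), at 36.9.

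Joining peaks within 12.5 kb gave 22772 regions, of which 574 had at least 10 kb covered by peaks. The largest lay over Msi2, an RNA-binding protein gene of neural progenitors (chromosome 11, 88232940 to 88730304), with 208 peaks covering 235.0 of 497.4 kb. In replicate 1 its peaks covered 196.7 kb and in replicate 2 205.6 kb. Next were Gse1 (159.3 kb covered, chromosome 8), the stretch of chromosome 2 from 30591181 to 30876865 with the starts of 1700001O22Rik, Cstad, Prrx2, Asb6 and Ntmt1 (113.8 kb), and Zmiz1 (84.0 kb, chromosome 14). Zfp423, a zinc finger gene needed for cerebellar development (64.4 kb, chromosome 8), and the corepressor gene Ncor2 (61.6 kb, chromosome 5) followed. The HoxB region from 96282941 to 96356303 ranked 7 with 59.2 of 73.4 kb covered, and the HoxA region ranked 15 with 45.4 of 50.3 kb. Mvb12b (54.1), Ttc28 (52.2), Bahcc1 (52.2), Cxxc5 (51.7), Rai1 (49.9) and Ahdc1 (46.7) lay between them by kb covered. The region at rank 13, chromosome 7 from 79495774 to 79551128, held no protein-coding start. It held the start of Mir9-3hg, a host gene of the neural microRNA miR-9, with those of other long non-coding genes, and had 49.4 of 55.4 kb covered by 5 peaks. Of these 15 regions, 9 overlapped one of the top 15 when peaks within 20 kb were joined, 9 in replicate 2 alone and 10 in replicate 1 alone.

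Differences in promoter fold between the replicates were small for most genes. Over 11666 genes the median log2 ratio of replicate 1 over replicate 2 was -0.11 with an SD of 0.41. The largest ratio was that of Rhof (53.0 against 3.65), where the replicate 1 peak reaches its promoter window and covers the start of Setd1b. Replicate 2 reached 38.3 over the same region, in a peak that does not reach the promoter window of Rhof. Rfc1 (8.48 against 2.37), Naxe (8.45 against 2.46), Wdr24 (7.89 against 2.46) and Trex1 (8.77 against 3.22) followed. At the other end were Fbxl22 (3.04 against 13.5), Enkur and its neighbour Thnsl1 with a shared peak (2.62 against 9.75), Slc4a10 (3.21 against 10.5) and Rbm34 (3.08 against 10.1). Of 22 lists with enough members, 1 was apart from matched random lists: neural crest and sensory ganglia, with a median log2 ratio of 0.23 over 11 genes (percentile 98.2). Chance puts 5% of lists apart.

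Chromosome X carried fewer peaks than the autosomes in these pools of mixed sex. It had 4.61 replicated peaks per Mb against 22.0 on the autosomes, a ratio of 0.210, and 0.171 and 0.174 in the replicates alone. Of its genes 36.4% had a promoter peak, against 55.6% of autosomal genes. Among autosomes, peaks per Mb ranged from 15.5 on chromosome 3 to 36.8 on chromosome 11. Chromosome Y had 2 replicated peaks.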

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

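Peaks on unplaced scaffolds were used in no comparison. The replicated list held 9 of them, with folds from 2.52 to 29.5. No biological explanation was tested for them.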

How the results depend on the processing

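No paired analysis was possible because the series has 1 group. The overlap of the replicates passed under all 6 alternatives, from 32.5% to 85.1% of peaks. Not merging entries, 1 of these 6, could change nothing, since no entries overlapped or touched. The 50% rule for retention could change nothing either, since every replicated peak was an entry of the combined list. The promoter and intergenic shares, the difference between anterior and posterior Hox genes (58.3 to 83.3 points, lowest with 1 start per gene, which was chosen after seeing the data) and the difference in distal peaks between hindbrain and forebrain regulators (9.77 to 19.1) kept direction and call under every alternative run on them. Of the 113 named genes with a promoter peak, 103 to 113 kept it under other promoter windows and other peak lists, and 96 with 1 start per gene. Lists called higher numbered 7 to 9 and lists called lower 5 to 9. Lists high in distal peaks numbered 7 to 15, and 7 of the 10 were among those of each replicate alone. The number of large regions was 18350 to 30205. No alternative matched the comparison of hindbrain and forebrain distal peaks on territory length. Where calls changed, the cause was not tested.

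With −log10 q of at least 5, Spearman's rho was 0.730, the exon (2.78%) and intron (34.6%) shares reversed to below the shifted means, floor plate genes reversed to 50%, and forebrain (28.0%) and oligodendrocyte (16.7%) genes became lower. The difference between hindbrain and forebrain promoters, 28.2 points in the main result, passed at 35.6 points. Rho was 0.622 for shared peaks without the replicated list and 0.774 for −log10 p. With a 2.5 kb window the exon share (2.29%) and the endothelium (28.6%) and muscle (23.1%) calls were lost. With 1 start per gene, anterior Hox genes fell from 83.3% to 58.3%, middle Hox genes reversed to 36.4%, the hindbrain and forebrain difference passed at 32.2 points (chosen after seeing the data), the Hedgehog call was lost (83.3%), and cell cycle (82.4%) and epidermis (0%) passed. In the combined list, hindbrain (90.9%) and cell cycle (88.2%) genes passed as higher, the hindbrain and forebrain difference passed (50.9 points), the endothelium call was lost (50%), motor neuron genes reversed to 60%, and the X to autosome ratio was 0.158. Counting long non-coding starts, an alternative chosen after seeing the data, lowered the distal share from 65.1% to 60.4%. Joining within 20 kb left 9 of the 15 largest regions.

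In either replicate alone, the ranges were 77.3% to 86.4% for hindbrain, 61.5% to 69.2% for neurotransmitter (reversed), 50% to 60% for motor neuron (reversed in replicate 1), 82.4% to 88.2% for cell cycle, 81.2% to 93.8% for mesenchyme and 28.6% to 35.7% for endothelium genes. They were 37.3 to 38.4 points for hindbrain against forebrain, 9 to 10 of the 15 largest regions, and 0.171 to 0.174 for X over autosomes. Depth is unknown, so how far it limits the weaker peaks cannot be stated.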

Other observations

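The test on the share of distal peaks at long non-coding starts, the look at microRNA host genes and the CpG tests on redrawn lists were chosen after the data were seen. Of 34692 distal peaks, 1379 (3.97%) had a midpoint within 1 kb of a long non-coding start, against 1.13% of shifted peaks (highest of 100 shifts, 1.32%). The share was 9.92% in the top 10% by fold and 2.74% in the lowest 10%, a ratio of 3.62. Part of the strongest distal peaks may thus be promoters of genes counted here as non-coding. That set held Zswim6 and Trerf1, which were missing from the protein-coding set. Whether wide peaks reach a start by their length was not decided, since the share counts midpoints and so leaves length out, and the 6.69 times higher share among the 71 narrow peaks of the top 10% adds nothing to it. MicroRNA host genes were picked by symbols that start with Mir and end in hg, so hosts under other symbols were missed. Of the 10 picked, 7 had a replicated peak within 1 kb of a start: Mir124-2hg (36.9), Mir124a-1hg (33.4), Mir9-3hg (26.3), Mir17hg (26.1), Mir99ahg (15.6), Mir22hg (7.70) and Mir670hg (5.40). Mir133a-1hg, Mir142hg and Mir155hg had none. Of the top 10% by fold, most had no midpoint near a long non-coding start, and no biological explanation was tested for these.

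CpG-rich promoters had peaks far more often than CpG-poor ones, 94.5% in the top 10% by number of CpGs within 500 bp of a start against 0.410% in the lowest 10%, so CpG number was tested as the whole cause of the list calls. Because the called lists were picked on the same peaks, all 30 lists were redrawn 5000 times, matched on CpG number, and put through the same calls. On average 5.74 redrawn lists were called higher, against 7 observed. Lists called lower other than Hox numbered 2.31 on average, against 6 observed. Calls were thus common among CpG-matched random lists, and the number of higher calls alone says little. The 7 higher lists lay 19.2 points above their matched mean, outside the middle 95% of redrawn called lists (2.73 to 11.5), and the 6 lower lists other than Hox at -16.4 points (-14.3 to 4.80), while the posterior Hox list, a list fixed beforehand, had 0% against a matched mean of 80.4%, a difference of -80.4 points, all of which argues against CpG number as the whole cause for each set as a whole. Taken singly, 4 of the 7 higher lists (differentiating neuron, axon guidance, housekeeping, mesenchyme and meninges) were apart after matching. So were 3 of the 7 lower ones (posterior Hox, endothelium and pericyte, germ cell). Neural progenitor, Notch, Hedgehog, erythroid, microglia, muscle and hepatocyte genes were not. Notch at 100% could not come out high and hepatocyte at 0% could not come out low, since their matched ranges reached those values. Hedgehog and microglia genes had little room to. Housekeeping (percentile 97.7), endothelium (1.57) and muscle (2.75) genes sat on the edge of their matched ranges, so their calls rest on how ties count. So did the list for midbrain and the midbrain-hindbrain boundary (61.5% against 82.0%, percentile 2.94), which had no call and is not counted as low below. Of the 16 lists without a call, 4 were low once matched, namely forebrain (40.0% against 77.3%), motor neuron (30.0% against 75.4%), roof plate and choroid plexus (30.8% against 58.2%) and Wnt pathway genes (57.9% against 85.0%), and no explanation was tested for these 4.

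Chromosome X had fewer peaks than the autosomes. Per gene with a promoter peak, X had 0.293 times the autosomal number of distal peaks (bootstrap 95% interval 0.185 to 0.460), and 0.682 times for those of the top 10%, with a fold of at least 6.53 (0.359 to 1.17, 70 peaks on X). Weak peaks missed at lower coverage of X would bring the second ratio near 1, which lies within its interval. Loss of the mark on the inactive X of female embryos could lower folds on X, where the median promoter fold was 0.803 times the autosomal one (0.742 to 0.869), but strong distal peaks on X were 2.01 times as many as autosomal ones of 1.5 times the fold (1.06 to 3.47), an interval that includes part of the range this explanation needs, which is close to 1. With 70 peaks these 2 explanations cannot be told apart.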
